A study of Mus musculus with 8 samples.

How the data were processed

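Bulk RNA sequencing of mouse skin keratinocytes was analysed from 8 libraries, 4 from InvEE mice with floxed Hmgb1 and no K5-Cre (control) and 4 from InvEE mice with floxed Hmgb1 and K5-Cre (knockout). InvEE mice carry an activated form of the kinase MEK1 under the involucrin promoter, and K5-Cre deletes floxed sequence in basal keratinocytes and the cells that descend from them. The labels give the strain as CBA x C57Bl/6J and the molecule as total RNA. They number the replicates within each genotype without stating that each is a separate animal, so p-values measure the spread between these libraries, which may be partly technical. Knockout replicate 4 was identified by its sample title, which carries another number than the name of its deposited file.

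The deposited values were whole-number counts per gene symbol, with no normalization, for 24421 symbols in each library. FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0, SAMtools 0.1.18 and the mouse build mm10 are named in the submitters' processing notes. The counting tool, its annotation and its use of strand were not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and counts of near-identical gene copies are uncertain. Each deposited count file closed with lines that count reads outside genes and ambiguous reads, which were left out of library sizes and tests. Reads outside genes made up 15.7 to 21.75% of the total and ambiguous reads 0.918 to 1.11%. The line for multiply aligned reads was 0 in every library. Mitochondrially encoded genes were absent from the symbols read, and that list was therefore not analysed here.

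Library totals over genes ranged from 30506676 to 34229030 counts. Genes were filtered with edgeR's filterByExpr by group, which left 13016 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test with robust dispersion and genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Standard errors are those of the fitted log2 fold change, and CPM use the TMM-scaled library sizes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Of the tested symbols, 12429 (95.5%) were found in the RefSeq table of GRCm38.p6, the assembly of mm10, and coordinates come from that table.

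36 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Hmgb1, and the 10 genes with the largest positive and the 10 with the largest negative log2 fold change. These were taken among genes at an adjusted p under 0.05 whose groups did not overlap and whose mean was at least 2 CPM in a group. It then named up to 4 members of each list by smallest adjusted p, or the 2 members with the highest mean where none passed. Lists with at least 5 tested members, 31 in all, were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01) with Hmgb1 left out, and also with an estimated correlation and with fry. The mean of each list per library was compared by an exact two-sided permutation test over the 70 regroupings of the libraries, whose smallest possible p is 0.0286.

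The steps were tested on simulated counts drawn for 12910 genes from the means and sizes of these 4 control and 4 knockout libraries, with 50 genes changed at each fold. edgeR recovered 32% of genes changed 1.5-fold, 78% at 2-fold, 92% at 3-fold and 90% at 4-fold. Far fewer genes were changed there than were called in the data, so these shares need not hold for the data. Of its calls, 5.81% were genes simulated as unchanged, against 16.8% for DESeq2 and 6.58% for limma-voom. With no gene changed, camera called 0 of 31 lists; the simulation drew genes independently of each other, unlike genes in tissue. Alternatives were DESeq2, limma-voom with and without quality weights, RLE and upper-quartile scaling, library totals only, no filter on low counts, a filter of 1 CPM in 4 libraries, non-robust dispersion, the replicate number as a block, and each library left out in turn. A term for Y-linked transcripts, and a fit to the 5 libraries without them, were added after seeing the data.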

Results

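The transcriptome of skin keratinocytes was measured in 8 libraries to ask which transcripts differ when Hmgb1, a chromatin protein that also acts as an alarmin outside the cell, is deleted from keratinocytes of InvEE mice. Only the knockouts carried K5-Cre, so an effect of Cre itself cannot be told apart from that of losing Hmgb1. There were 4 control and 4 knockout libraries, with 30506676 to 34229030 counts on genes each. Totals did not separate the groups, at 32230000 ± 1920000 in controls and 31410000 ± 633000 in knockouts (SD, n = 4 each, exact permutation p = 0.486). The TMM scaling factors did, at 1.038 ± 0.0175 in controls and 0.964 ± 0.0449 in knockouts (SD, n = 4 each, exact permutation p = 0.0286). Fewer genes were detected in knockouts, 15780 ± 106 against 16090 ± 168 (SD, n = 4 each, exact permutation p = 0.0286, the smallest p this design allows). Correlations between libraries were 0.972 to 0.990 within a genotype and 0.962 to 0.981 between genotypes. The first principal component held 49% of the variance of the 500 most variable genes and had all controls below 0 and all knockouts above 0. Y-linked transcripts were present in control replicates 2 and 3 and knockout replicate 1, with 6110 to 6743 counts summed over the Y-linked genes listed. The other libraries had 0 and 2 counts (control replicates 1 and 4) and 6, 26 and 51 (knockout replicates 2, 3 and 4). Xist was at 1283 to 2323 CPM in those others. In the libraries with Y-linked transcripts it was at 0.224 and 0.370 CPM in controls and 4.91 CPM in the knockout. The sexes were therefore unevenly spread over the groups, and the labels do not give them.

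Hmgb1 (chromosome 5, 149046702 to 149053057, mm10) fell in every knockout library. It was at 591 ± 21.03 CPM in controls and 118 ± 5.87 CPM in knockouts (SD, n = 4 each), a log2 fold change of -2.32 (SE 0.09, edgeR adjusted p = 3.576e-07, exact permutation p = 0.0286). Controls ranged from 565.5 to 615.0 CPM and knockouts from 113.4 to 126.2 CPM, so 19.97% ± 0.993 (SD, n = 4) of the control level remained. Which exons the floxed allele loses was not given in the sources used here, and Hmgb1 has many near-identical processed copies in the genome, so the remaining counts are uncertain. Of the other chromatin proteins of the HMG families, Hmgn1 was at 541 ± 5.71 CPM in controls and 574 ± 46.9 CPM in knockouts, and Hmgb2 at 302 ± 12.1 and 313 ± 23.8 CPM (SD, n = 4 each). No other tested member of that list passed the test among 11, 1 of which had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0.

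**Figure D1:**
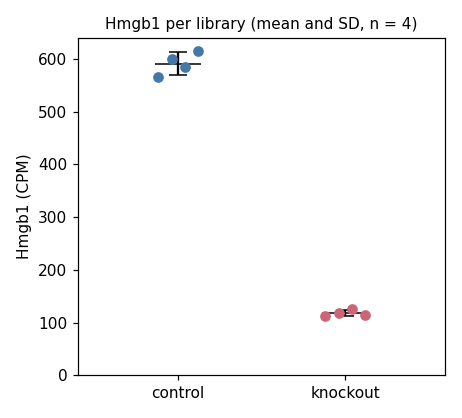
Hmgb1 in CPM (vertical axis from 0) for each of the 4 control and 4 knockout libraries (points), with the mean and SD of each group (bars). The knockout libraries lie between 113.4 and 126.2 CPM, all below the controls at 565.5 to 615.0 CPM.

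Beyond Hmgb1, Ifi44, Oas2 and Edn2 had the largest rises in the knockout, and Plscr4 and C1s1 were among the 10 genes with the largest falls. Ifi44, an interferon-induced gene, rose from 4.59 ± 3.54 to 40.6 ± 32.6 CPM (SD, n = 4 each, 8.86-fold), and Oas2, an oligoadenylate synthetase that senses double-stranded RNA, rose 8.49-fold (log2 3.09, SE 0.75). Edn2, which encodes a vasoconstrictor peptide, rose from 4.85 ± 3.06 to 36.4 ± 18.5 CPM (7.47-fold, adjusted p = 0.01617). Plscr4, a phospholipid scramblase, fell from 8.53 ± 2.48 to 0.518 ± 0.258 CPM, 16.4-fold lower (log2 -4.04, SE 0.37, adjusted p = 0.0005796). C1s1, a protease of the classical complement pathway, fell from 30.3 ± 7.11 to 4.22 ± 0.729 CPM, 7.17-fold lower.

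Across 13016 tested genes, 1154 differed at an adjusted p under 0.05 (edgeR quasi-likelihood), 563 higher and 591 lower in the knockout. Of the 418 genes that differed at least 2-fold, 132 were higher and 286 lower. The groups did not overlap for 17% of tested genes, against 2.86% by chance. The other genes of the 10 with the largest rise were Slfn2, Atg9b, Gapdhs, Oas3, Apol9a, Mx2 and the complement component C2, with log2 fold changes of 2.36 to 2.73. Gapdhs, the glycolytic enzyme of sperm, rose from 2.25 ± 0.331 to 13.7 ± 2.32 CPM (log2 2.61, SE 0.17), and its annotated span overlaps that of Sbsn, an abundant epidermal gene that also rose (451 ± 126 to 897 ± 176 CPM). Besides Plscr4 and C1s1, the genes with the largest fall were Ica1, Lrrn3, the epidermal keratin Krt2 and the receptor phosphatase Ptprz1. They also included the clathrin-uncoating factor Dnajc6, the protein kinase A subunit Prkar2b, the tubulin-modifying enzyme Ttll7 and the phosphatase inhibitor Ppp1r14a. These 8 had log2 fold changes of -4.04 to -2.85. Dnajc6 had the smallest adjusted p among these, 7.34e-05, and went from 3.43 ± 0.454 to 0.322 ± 0.055 CPM (SD, n = 4 each). Calls for Atg9b, Gapdhs, Mx2, Plscr4, Ica1, Lrrn3, Dnajc6, Prkar2b, Ttll7, Ppp1r14a and C1s1 held in all 8 fits that left out 1 library. Ptprz1 and Edn2 each lost the call in 1 of those fits (adjusted p = 0.06108 without knockout replicate 2, and 0.05834 without control replicate 2), Slfn2 in 3, Ifi44 and Krt2 in 6, Oas2 and Oas3 in 7, and Apol9a and C2 in 8. The count of genes fell to 550 without control replicate 2, 769 without control replicate 4, 718 without knockout replicate 1 and 462 without knockout replicate 2. With library totals only in place of TMM, which moved the median log2 fold change by -0.11, 370 genes were higher and 997 lower.

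**Figure D2:**
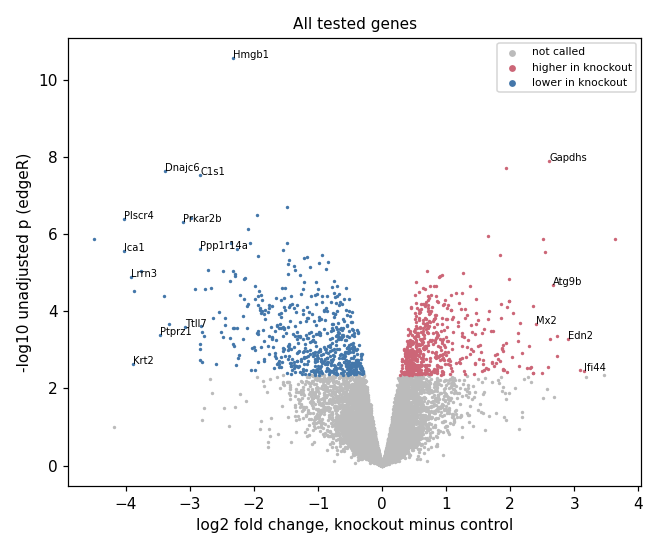
Each point is 1 of the 13016 tested genes, with the log2 fold change (knockout minus control) on the horizontal axis and -log10 of the unadjusted edgeR p on the vertical axis. The 563 genes called higher are red, the 591 called lower are blue, and Hmgb1 stands highest.

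**Figure D3:**
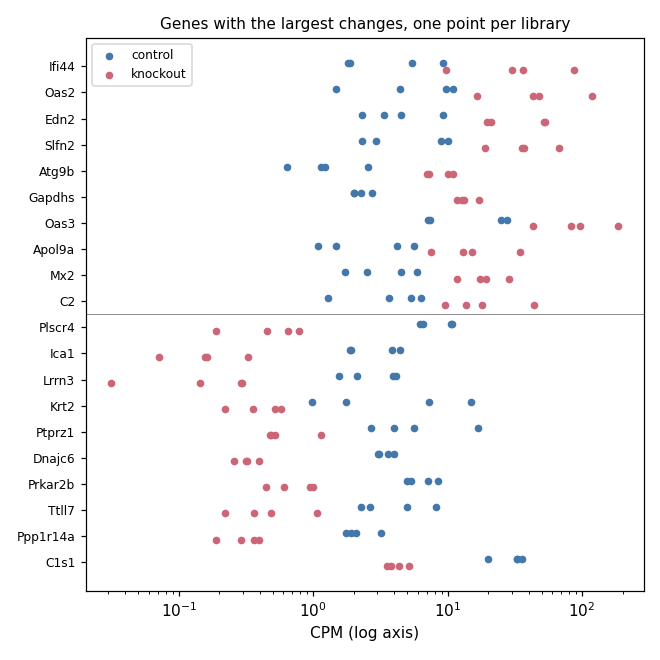
CPM on a log axis for the 10 genes with the largest rise (above the line) and the 10 with the largest fall (below), 1 point per library, 4 control and 4 knockout. The groups do not overlap for any of the 20 genes, which the rule for named genes required. The interferon-induced genes Ifi44, Oas2 and Oas3 spread widely within both groups.

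The type I interferon response was the list with the largest change: 20 of its 33 tested members rose and 13 did not pass the test, with a median log2 fold change of 1.83. Adjusted over the list alone, 31 members were higher. Irf9, a transcription factor of the interferon pathway, rose from 51.5 ± 17.5 to 131 ± 30.8 CPM (SD, n = 4 each, adjusted p = 0.01683). The RNA sensor regulator Dhx58 rose from 6.86 ± 3.10 to 33.6 ± 17.5 CPM (adjusted p = 0.02111). Mx2, an interferon-induced GTPase, rose from 3.66 ± 1.90 to 19.3 ± 7.10 CPM, and Oas1g from 4.55 ± 1.91 to 16.7 ± 7.36 CPM. Near-identical copies in the Oas1 family make the count of a single member uncertain. Camera called the list higher (adjusted p = 3.88e-17), and that call was lost with an estimated correlation (adjusted p = 0.50 with an estimated correlation). The mean of the list per library did not overlap between groups (exact permutation p = 0.0286, n = 4 each). Library means differed widely within genotypes, with an SD of 0.667 (log2) in controls and 0.722 in knockouts. The count of members called higher went from 20 to 4, 10, 5 and 9 without control replicates 1, 2, 3 and 4 and to 1, 11 and 6 without knockout replicates 2, 3 and 4. With a term for Y-linked transcripts 6 members were called, and 8 in the 5 libraries without them. The interferon genes themselves, given outside the naming rule, were near the floor. Ifnb1 was at 0.0991 ± 0.0827 CPM in controls and 0.11 ± 0.11 CPM in knockouts. Others had higher means in knockouts: Ifnk at 0.0303 ± 0.0239 and 0.0927 ± 0.0706 CPM, Ifnl2 at 0.401 ± 0.33 and 0.588 ± 0.329 CPM, and Ifnl3 at 0.268 ± 0.243 and 0.535 ± 0.224 CPM (SD, n = 4 each).

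Of 24 tested cholesterol synthesis genes, 12 were called higher in the knockout and 12 did not pass, with a median log2 fold change of 0.81 (18 higher when adjusted over the list alone). Mvd, an enzyme of the mevalonate pathway, rose from 13.2 ± 3.85 to 32.5 ± 5.21 CPM (SD, n = 4 each, 2.46-fold, adjusted p = 0.006936). Sqle, squalene epoxidase, rose from 94.1 ± 15.2 to 189 ± 46.2 CPM, Sc5d from 57.1 ± 16.7 to 130 ± 22.8 CPM and the sterol carrier Stard4 from 27.2 ± 6.18 to 57.2 ± 9.40 CPM. Camera gave an adjusted p of 3.45e-11 for this list and 1.74e-06 for the epidermal lipid barrier list, against adjusted p = 0.414 and 0.567 with an estimated correlation. Of 25 tested lipid barrier genes, 5 rose and 20 did not pass (14 higher when adjusted over the list alone). Among those that rose were Ugcg, which makes glucosylceramide (42.2 ± 7.94 to 83.2 ± 24.5 CPM), Asprv1, a protease that processes filaggrin (71.1 ± 22.1 to 203 ± 90.5 CPM), Cyp4f39 and Nipal4. Without knockout replicate 1 the cholesterol count was 7. The lipid barrier count was 2, 1 and 1 without control replicates 1, 2 and 3 and 1, 1 and 8 without knockout replicates 1, 2 and 3, and it was 0 by edgeR in the 5 libraries without Y-linked transcripts.

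Among genes of the differentiated upper epidermis, Krt10 rose from 5094 ± 1265 to 9022 ± 1301 CPM (SD, n = 4 each, adjusted p = 0.01693) and Sbsn also rose. Krt2, at a far lower level, fell from 6.25 ± 6.45 to 0.418 ± 0.161 CPM. It was at 14.95 and 7.30 CPM in control replicates 2 and 3, which had Y-linked transcripts, and at 0.977 and 1.75 CPM in control replicates 1 and 4. The other 26 of 29 tested members of this suprabasal list did not pass, the counts were the same when adjusted over the list alone (2 higher, 1 lower), and the median log2 fold change was 0.27. Camera called the list higher (adjusted p = 0.0109; adjusted p = 0.704 with an estimated correlation), and that call was lost without control replicate 1 (adjusted p = 0.107), control replicate 2 (adjusted p = 0.348) or knockout replicate 2 (adjusted p = 0.0589), and in the 5 libraries without Y-linked transcripts (adjusted p = 0.357), where 0 members were called by edgeR. DESeq2 called 8 members higher and limma-voom with quality weights 7. The median was 0.025 without control replicate 2 (1 member higher) and 0.552 without control replicate 4 (4 members higher). Krt10 lost its call in 2 of the 8 fits that left out 1 library. Of 16 tested basal keratinocyte genes, edgeR, DESeq2 and limma-voom called 0, and 2 had an unadjusted p under 0.05. With library totals only edgeR called 2 lower, and limma-voom with quality weights called 1 lower. Krt5 was at 23793 ± 2051 CPM in controls and 24214 ± 1984 CPM in knockouts, and Krt14 at 17727 ± 1413 and 17438 ± 1817 CPM (SD, n = 4 each). In the wound and hyperproliferation list, of 14 tested members, Krt16 rose from 1020 ± 181 to 1822 ± 436 CPM. The cystatin gene Stfa3, one of several near-identical copies, fell from 723 ± 312 to 110 ± 18.1 CPM (2 higher and 2 lower when adjusted over the list alone).

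Of 27 tested hypoxia and glycolysis genes, 6 were called higher in the knockout and 21 did not pass (16 higher when adjusted over the list alone, median log2 fold change 0.39). The glucose transporter Slc2a1 rose from 250.5 ± 33.2 to 441 ± 98.0 CPM (SD, n = 4 each, adjusted p = 0.01169) and the carbonic anhydrase Car9 from 3.07 ± 0.803 to 8.09 ± 2.62 CPM. The glycolytic enzymes Gpi1 and Pgk1 rose 1.32-fold and 1.39-fold. Camera gave an adjusted p of 6.05e-09, and adjusted p = 0.414 with an estimated correlation. Of 24 tested p53 targets, 6 rose and 18 did not pass (11 higher and 1 lower when adjusted over the list alone). Those that rose include the cell cycle inhibitor Cdkn1a (255 ± 51.4 to 411 ± 48.4 CPM), the stress-induced mTOR inhibitor Ddit4 (38.5 ± 5.47 to 71.4 ± 7.84 CPM), Aen and Phlda3. The p53 list had a camera adjusted p of 0.000249, adjusted p = 0.255 with an estimated correlation and adjusted p = 0.014 by fry. The estimated correlation was 0.017, close to the preset 0.01, so correlation between members alone does not account for the lost call. Without knockout replicate 1 the hypoxia and p53 counts were each 3, and without knockout replicate 2 the p53 count was 3.

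Of 32 tested G2 and M phase genes, 3 rose and 29 did not pass (3 when adjusted over the list alone). The 3 were Ckap2l (99.1 ± 2.86 to 144 ± 5.99 CPM), Anln (308 ± 14.5 to 443 ± 33.9 CPM) and Cdc20, the activator of the anaphase-promoting complex (113 ± 8.30 to 149 ± 9.16 CPM). Of 30 tested S phase genes, Rrm2, a subunit of ribonucleotide reductase, fell from 86.7 ± 18.7 to 52.6 ± 4.35 CPM and 29 did not pass (1 when adjusted over the list alone). Camera called the first list higher (adjusted p = 0.00144) and the S phase list lower (adjusted p = 0.00542), each with adjusted p = 0.704 with an estimated correlation. List means overlapped between the groups for both (exact permutation p = 0.143 and 0.0857, n = 4 each), with the G2 and M phase mean of knockout replicate 1 at -0.116, below all controls. The S phase call was lost without control replicate 4 (adjusted p = 0.0518) and in the 5 libraries without Y-linked transcripts (adjusted p = 0.132). S phase genes called lower were 3 with DESeq2, 4 with library totals only or quality weights, and 0 to 3 leaving out 1 library. G2 and M phase genes called higher were 5 with quality weights. Leaving out 1 library, Rrm2 lost its call in 3 of 8 fits and Cdc20 in 2. Autophagy genes had a camera adjusted p of 0.0109 (adjusted p = 0.567 with an estimated correlation), but edgeR called 0 of 24 members over all genes and 6 adjusted over the list alone. Of these 24, 8 had an unadjusted p under 0.05, and DESeq2 called 6, limma-voom 0 and limma-voom with quality weights 5. The camera call was lost in the 5 libraries without Y-linked transcripts (adjusted p = 0.0929). The abundant lysosomal members Lamp1 and Lamp2 were at 433 ± 36.7 and 329 ± 48.3 CPM in controls and 529 ± 32.1 and 343 ± 31.1 CPM in knockouts (SD, n = 4 each).

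Of 25 tested hair follicle stem and matrix genes, 3 fell, 1 rose and 21 did not pass. Lgr5 fell from 17.0 ± 6.37 to 3.98 ± 1.25 CPM (SD, n = 4 each, 4.26-fold lower, adjusted p = 0.006426). Lrig1 fell from 211 ± 25.3 to 125 ± 13.3 CPM and Lgr6 from 76.1 ± 13.3 to 47.3 ± 4.19 CPM. These genes mark stem cells of the follicle, but other such genes on the list did not pass. Nfatc1, Sox9 and Cd34 are given here outside the naming rule, picked after their values were seen. Nfatc1 was at 121.5 ± 14.3 CPM in controls and 125 ± 24.6 CPM in knockouts, and Sox9 at 93.2 ± 20.7 and 76.5 ± 10.3 CPM. Cd34 was at 48.2 ± 15.2 and 20.3 ± 11.1 CPM (edgeR adjusted p = 0.07371). Gata3, a regulator of the inner root sheath that is also active in the epidermis between follicles, rose from 272 ± 78.2 to 513 ± 117 CPM. Adjusted over the list alone, 7 were lower and 1 higher. Camera called the list lower (adjusted p = 0.00347; adjusted p = 0.414 with an estimated correlation), and 5 members were called lower without control replicate 3 or without knockout replicate 3, 8 with DESeq2 and 7 with limma-voom with quality weights. Gata3 lost its call in 4 of the 8 fits that left out 1 library.

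**Figure D4:**
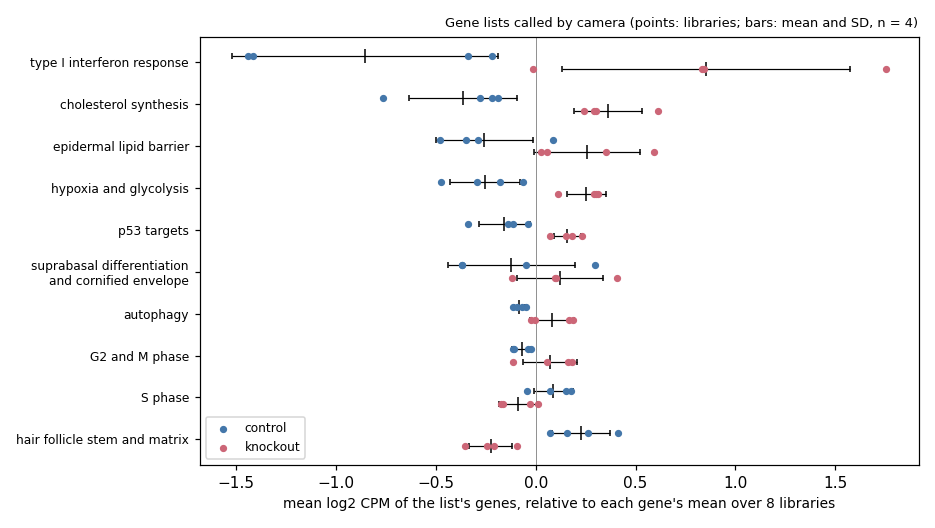
Mean log2 CPM of the genes of each of the 10 lists called by camera (horizontal axis, relative to each gene's mean over the 8 libraries), 1 point per library, with the mean and SD of the 4 control and 4 knockout libraries. The interferon list has the widest gap, 1.71, and the widest spread within each genotype, with SDs of 0.667 and 0.722.

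In all, camera called 10 of 31 lists, 8 higher and 2 lower, and 0 with an estimated correlation. Among the 10 lists, that estimate ran from 0.017 for p53 targets to 0.799 for the interferon list. With fry, 7 lists were called. Of those 7, 5 were among the 10 and 2 were not, HMG chromatin proteins (adjusted p = 0.014) and neutrophil chemoattractants and growth factors (adjusted p = 0.0175). At least 10 lists were also called in 14 of the 35 ways to split the 8 libraries into groups of 4, the genotype split included. By the exact permutation test of list means, 8 of 34 lists reached the smallest possible p of 0.0286, which adjusts to 0.122 over the lists. Of these 8, 6 were called by camera, and HMG chromatin proteins and neutrophil chemoattractants and growth factors were not. The other 4 lists called by camera were the lipid barrier (exact permutation p = 0.0857), suprabasal (0.229), G2 and M phase (0.143) and S phase (0.0857) lists.

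Of 5 tested neutrophil chemoattractants and growth factors, Cxcl1, which draws neutrophils, fell from 8.07 ± 2.26 to 3.62 ± 0.810 CPM. The complement component C3 fell from 6.52 ± 2.59 to 2.15 ± 0.377 CPM (SD, n = 4 each; 2 lower adjusted over the list alone; camera adjusted p = 0.139). Of 27 other cytokines and chemokines Il6 fell (3.28 ± 1.39 to 1.12 ± 0.264 CPM). Members of that list called lower were 0 to 3 leaving out 1 library and 3 in the 5 libraries without Y-linked transcripts. Of 21 NF-kB targets Vcam1 and Sod2 fell, with the same counts adjusted over each list alone and camera adjusted p of 0.717 and 0.869. Of 7 antimicrobial and alarmin genes the interleukin 1 receptor antagonist Il1rn rose from 80.8 ± 7.07 to 120 ± 11.8 CPM (2 higher and 1 lower adjusted over the list alone). Of 25 genes of TNF receptor signalling and cell death Traf2 rose (1 adjusted over the list alone). Of 11 tested HMGB1 receptors and adaptors the toll-like receptor adaptor Tirap fell from 2.92 ± 0.813 to 1.52 ± 0.339 CPM (1 adjusted over the list alone). Of 26 ERK pathway targets, the feedback inhibitors Spry2 (18.03 ± 0.793 to 12.4 ± 0.685 CPM) and Dusp6 (326 ± 93.9 to 180 ± 29.5 CPM) fell (5 lower and 1 higher adjusted over the list alone). DESeq2, library totals only and quality weights each called 6 of these targets lower, and fits that left out 1 library called 1 to 4. The Dusp6 values overlapped between groups. Of 26 immediate-early and heat shock genes, which also respond to tissue dissociation, Nr4a2, Klf4 and Dusp1 fell and Hspb1 rose (5 lower and 1 higher adjusted over the list alone). Fosb, named after its values were seen, also fell (log2 -0.61, adjusted p = 0.0497), a call lost in 7 of the 8 fits that left out 1 library, with RLE scaling, limma-voom, non-robust dispersion and the replicate block, and in the 5 libraries without Y-linked transcripts. In the wound matrix and protease list, of 20 tested members the integrin Itgb6 rose (2 adjusted over the list alone).

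Of 12 macrophage, monocyte and mast cell genes Kit fell (0.732 ± 0.229 to 0.129 ± 0.067 CPM), and of 15 fibroblast genes Col5a2 fell and Dcn rose. Of 7 endothelial, pericyte and smooth muscle genes Acta2 rose (1.13 ± 0.365 to 3.60 ± 0.730 CPM). Of 9 melanocyte and Schwann cell genes Mitf fell and Mbp rose (SD, n = 4 each). Of 6 hair shaft and inner root sheath genes Krtap3-2 rose, and of 17 sebaceous gland genes Scd3 fell, with 0 called adjusted over the list alone. edgeR called 0 of 13 Langerhans and dendritic cell, 7 T and innate lymphoid, 3 neutrophil, 6 skeletal muscle, 4 adipocyte, 1 erythrocyte and 3 sex-linked genes. At an unadjusted p under 0.05 these lists had 2, 2, 1, 0, 1, 0 and 0 members, DESeq2 called 2, 1, 0, 0, 0, 0 and 0, and limma-voom 0 in each. With quality weights limma-voom called 1 Langerhans and dendritic cell gene and 0 in the other lists. Cd74, carried by antigen-presenting cells, was at 24.5 ± 12.5 CPM in controls and 20.6 ± 9.37 CPM in knockouts, and the neutrophil receptor Cxcr2 at 5.69 ± 2.89 and 5.58 ± 0.748 CPM (SD, n = 4 each). Others that did not pass were higher in CPM: Thy1 at 209 ± 30.5 and 280 ± 45.4, Il2rg at 55.3 ± 15.1 and 47.6 ± 5.54 and Il1r2 at 71.0 ± 17.7 and 81.1 ± 10.1. Camera called none of these cell type lists that it tested (adjusted p from 0.583 to 0.962), nor the HMG, HMGB1 receptor, basal, wound, ERK, immediate-early or other lists named above without a call. Among these, the wound list was called without control replicate 3 (adjusted p = 0.0248) and in the 5 libraries without Y-linked transcripts (adjusted p = 0.0356). The immediate-early list was called without control replicate 3 (adjusted p = 0.0263) and without knockout replicate 4 (adjusted p = 0.0353). The median, the mean and the camera direction differed in sign for 10 lists, all of them uncalled. They were HMGB1 receptors and adaptors, basal keratinocyte, wound and hyperproliferation keratinocyte, antimicrobial and alarmin, other cytokines and chemokines, NF-kB targets, wound matrix and protease, hair shaft and inner root sheath, Langerhans and dendritic cell, and skeletal muscle.

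Several of the calls for named genes were lost in other fits. Leaving out 1 library, Dusp6 and Dusp1 lost the call in 7 of 8 fits (adjusted p up to 0.09967 and 0.1335), and Tirap, Sod2, Itgb6 and Scd3 in 6 (up to 0.135, 0.1249, 0.1009 and 0.1208). Ugcg, Asprv1 and Cyp4f39 lost it in 5 of 8, and Krt16, Pgk1 and Krtap3-2 in 3. Klf4, Il6, Traf2, Dcn, Dhx58 and Cdkn1a lost it in 2, and Irf9 and Oas1g in 1. With the replicate number as a block, the calls for Ifi44, Edn2, Oas3, Apol9a, C2, Tirap, Krt16, Cxcl1, Sod2, Dusp6, Ugcg, Asprv1, Itgb6, Car9, Gpi1, Pgk1, Klf4, Dusp1 and Scd3 were lost. With the term for Y-linked transcripts, those for Ifi44, Oas2, Oas3, Apol9a, Tirap, Sod2 and Gata3 were lost. In the 5 libraries without Y-linked transcripts the calls for Edn2, Slfn2, Ifi44, Oas2, Oas3, Apol9a, C2, Krt2, Oas1g and Dhx58 were lost. Also lost there were Krt10, Sbsn, Krt16, Gata3, Rrm2, Anln, Cdkn1a, Nipal4, Cyp4f39, Ugcg, Asprv1, Car9, Gpi1 and Pgk1. The same held for Il1rn, C3, Cxcl1, Sod2, Traf2, Tirap, Spry2, Dusp6, Klf4, Dusp1, Krtap3-2, Scd3, Col5a2, Dcn, Mitf and Mbp. With library totals only, the calls for Ifi44, Oas2, Oas3, Apol9a, C2, Cdc20, Gpi1 and Pgk1 were lost, and in the upper quartile fit those for Ifi44, Oas2, Apol9a and C2. With no low-count filter, those for Ifi44, Oas2, Slfn2, Oas3, Apol9a, C2, Krt2, Sod2, Asprv1, Itgb6, Gata3 and Scd3 were lost. By limma-voom, Krt2 and Tirap were not called, and Krt2 was not called with quality weights.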

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

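A library was set apart where its gap to the nearest other library of its group was large against the range of the 4, a test that chance passes in about 1 of 20 groups. It was passed by 14 of 252 groups, against 12.6 by chance. Ptprz1 was at 1.15 CPM in knockout replicate 1, above 0.474 to 0.524 CPM in the other knockouts. In control replicate 4, Sbsn was at 639.5 CPM, Krt10 at 6988 CPM and Klf4 at 1763 CPM, above 375 to 404 CPM, 4367 to 4556 CPM and 1498 to 1542 CPM in the other controls. Lamp2 was at 401.5 CPM in control replicate 3, above 301 to 308 CPM. In knockout replicate 1, Sc5d was at 164 CPM and Itgb6 at 83.9 CPM, against 117 to 121 CPM and 42.2 to 44.6 CPM in the other knockouts. Il1rn was at 138 CPM in knockout replicate 2, above 113 to 116 CPM, and C3 at 2.72 CPM in knockout replicate 3, above 1.93 to 2.00 CPM. By list mean (log2, relative to all libraries), cholesterol synthesis stood at -0.767 in control replicate 3, below -0.28 to -0.19 in the other controls, and at 0.615 in knockout replicate 1, above 0.24 to 0.30 in the other knockouts. The hypoxia and glycolysis list stood at 0.109 in knockout replicate 2, below 0.29 to 0.31. The hair shaft and inner root sheath list stood at 0.56 in control replicate 1, and the sebaceous gland list at 0.115 in knockout replicate 4, each above the other libraries of its group.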

How the results depend on the processing

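The fits with a term for Y-linked transcripts and with only the 5 libraries without them were chosen after seeing the data; the others were planned. Hmgb1 kept its direction and its call in all of them, with log2 fold changes of -2.43 to -2.30. No gene called in the main test changed direction in any alternative. With 4 libraries a group, most genes changed 1.5-fold were missed in simulated counts (32% recovered). Far fewer genes were changed there than the 1154 called in the data, which makes the adjusted threshold stricter. The share missed in the data may therefore differ. The cause of the differences below was not tested.

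Against 1154 changed genes (563 higher, 591 lower), DESeq2 called 2010 (1093 and 917) and limma-voom with quality weights 1912 (955 and 957). With library totals only the split was 370 and 997. The 5 libraries without Y-linked transcripts gave 383 (141 and 242), 316 of them among the 1154, and the Y-linked term 1074, 930 of them among the 1154. Leaving out 1 library gave 462 to 1247 genes, 200 to 678 higher and 262 to 569 lower. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.228 to -0.053, and 0 libraries correlated best with their own number. With the replicate block 723 genes were called (375 higher, 348 lower), 658 of them among the 1154, and the block gave 10 interferon, 3 hypoxia and 2 lipid barrier members higher. Gene lists called by camera went from 10 to 0 with an estimated correlation and were 8 to 12 in the other fits where camera was run. It was not run with upper quartile scaling, library totals only, DESeq2, limma-voom, no low-count filter or non-robust dispersion.

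Interferon members called higher went from 20 to 12 with library totals only, 8 with no low-count filter, 6 with the Y-linked term, 8 in the 5 libraries and 1 to 26 leaving out 1 library. Cholesterol members ranged from 7 to 11 (12 in the main test) leaving out 1 library. Hypoxia members (6) went to 2 with library totals only, 14 with DESeq2, 2 in the 5 libraries and 3 to 6 leaving out 1 library. The p53 members (6) went to 10 with quality weights and 3 to 7 leaving out 1 library. Lipid barrier members (5) went to 13 with DESeq2, 12 with quality weights, 8 with the Y-linked term, 0 in the 5 libraries and 1 to 8 leaving out 1 library.

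Of the pairs of a named gene and an alternative, 1592 kept direction and side of the threshold, 227 lost the call, 6 gained one and 30 changed sign, all of the last for genes not called. Log2 fold changes with library totals only were -0.0247 for Hmgn1, -0.0543 for Hmgb2, -0.083 for Krt5 and -0.0553 for Lamp2. In the upper quartile fit the Hmgb2 log2 fold change was -6e-04 and that of Krt5 -0.0272. Krt5 was at -0.0295 with quality weights. Cxcr2 was at 0.0891 with limma-voom, 0.3103 with quality weights, 0.0815 with the replicate block, 0.0819 with the Y-linked term and 0.3636 in the 5 libraries. Krt14 was at 0.0209 with the Y-linked term and 0.013 in the 5 libraries. Ddx3y was at 0.3958 with limma-voom, 0.9684 with the Y-linked term and 6.6638 in the 5 libraries. Leaving out 1 library gave -0.0341 (without control replicate 1) to 0.074 (without knockout replicate 2) for Krt5 and -0.0724 to 0.0351 for Krt14. It gave -0.1828 to 0.3835 for Cxcr2, -0.5939 to 0.0901 for Cd74, -0.2136 to 0.111 for Pnpla2 and -6.7901 to 0.243 for Ddx3y.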

Other observations

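The genes in the first paragraph and all tests here except the count of splits were chosen after their values or the results they bear on were seen. The neurotrophin Bdnf fell from 1.71 ± 0.206 to 0.213 ± 0.048 CPM (SD, n = 4 each, edgeR adjusted p = 0.0005796). The prolactin receptor Prlr fell from 48.8 ± 10.8 to 17.4 ± 2.50 CPM and the insulin receptor substrate Irs1 from 13.4 ± 1.59 to 4.57 ± 0.985 CPM. Nog, a secreted BMP antagonist, fell 4.34-fold and Ngfr, a neurotrophin receptor, 2.57-fold. Mcam, a cell adhesion molecule, rose from 7.22 ± 1.12 to 27.7 ± 1.93 CPM (adjusted p = 7.34e-05). The clock repressor Nr1d1 rose from 41.8 ± 3.56 to 131 ± 32.2 CPM. The annotated span of Thra overlaps it, and Thra fell (log2 -0.32), a call lost in 7 of the 8 fits that left out 1 library, with RLE scaling, with no low-count filter, with the replicate block and in the 5 libraries without Y-linked transcripts. Map2k1, the gene of MEK1, rose from 110 ± 14.5 to 162 ± 16.7 CPM (adjusted p = 0.01501, not called in those 5 libraries), whereas Map2k2 was at 95.6 ± 6.30 and 93.2 ± 3.26 CPM. Whether the MEK1 transgene adds to the Map2k1 count is not known from these data.

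Chance was tested by splitting the 8 libraries into groups of 4 in all 35 ways. Only 1 split, the real one, gave 1154 or more changed genes, and the highest of the others gave 1. The other splits mix genotypes, so any difference between the groups adds to their spread and lowers their counts. An unlabelled litter or technical difference that follows genotype would give the same result. The count of genes therefore argues only against a random grouping of the libraries. For gene lists, 14 of the 35 splits gave at least the real 10 called lists, and the highest of the others gave 16, so chance cannot be excluded for the number of lists called by camera with its preset correlation.

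For the interferon list, higher in the knockout, the 32 tested immune markers gave no sign of more immune cells. Their median log2 fold change was -0.18, against 1.83 for the interferon list. Not all of these markers need be specific to immune cells, since Thy1 is also on the fibroblast list. The leukocyte gene Ptprc was near the floor, at 0.699 ± 0.333 CPM in controls and 0.46 ± 0.214 CPM in knockouts (SD, n = 4 each). For the uneven spread of the sexes, the list mean differed by 2.02 (SE 0.62, log2) within the 5 libraries without Y-linked transcripts. It was -1.415 and -0.338 in control replicates 1 and 4, and 0.832, 1.754 and 0.844 in knockout replicates 2, 3 and 4. The groups did not overlap, but so few libraries cannot settle whether sex is the whole cause. Knockout replicate 3 alone is argued against by a difference of 1.41 (SE 0.44) without it. An interferon state that differs between animals or litters stays open, since neither is labelled and the list mean varied widely within genotypes.

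A larger share of differentiated keratinocytes could raise the cholesterol and lipid barrier lists, both higher in the knockout. With the suprabasal list mean as a covariate, the group difference was 0.78 (SE 0.19, log2) for cholesterol synthesis, from 0.73 without it. For the lipid barrier it was 0.31 (SE 0.10), from 0.52. The covariate did not account for either rise in full. The suprabasal mean itself differed between the groups by only 0.244, with SDs of 0.318 in controls and 0.216 in knockouts (exact permutation p = 0.229). So weak a measure of that share cannot settle whether it is the whole cause. For cholesterol synthesis, scaling is argued against by a list mean of 0.60 with library totals only. For sex, the difference was 0.511 (SE 0.048) within the 5 libraries without Y-linked transcripts. The list mean was -0.188 and -0.277 in control replicates 1 and 4, and 0.241, 0.293 and 0.303 in knockout replicates 2, 3 and 4. The groups did not overlap, which argues against sex as the whole cause, but so few libraries cannot settle it. Control replicate 3 and knockout replicate 1, set apart above for this list, are not among these libraries. The lipid barrier difference was smaller after the adjustment, so part of it may go with differentiation. For the lipid barrier sex stays open, at 0.421 (SE 0.337) in those 5 libraries although 8 members were called with the Y-linked term in all libraries, and litter stays open for both lists.

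The 20 genes with the largest changes could reflect strain segments, since the mice were CBA and C57Bl/6J crosses. Both groups carry floxed Hmgb1, so a segment next to it has no reason in the design to differ, and a segment that travels with the Cre transgene was not tested. Of the 20 genes, 12 had another called gene of the same direction within 1 Mb, against a median of 10 for random sets of 20 genes (one-sided permutation p = 0.291). Strain segments and genotype therefore cannot be told apart for these genes, and genomic sequence was not analysed here.

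Of 41 tested imprinted genes, 8 were called lower in the knockout and 1, Osbpl5, higher (152 ± 5.16 to 189 ± 8.54 CPM, SD, n = 4 each). The Osbpl5 call was lost in 6 of the 8 fits that left out 1 library, with upper quartile scaling, library totals only and the replicate block, and in the 5 libraries without Y-linked transcripts. Among the 8 were Peg3 (3.51 ± 1.01 to 0.697 ± 0.187 CPM, SD, n = 4 each), Slc38a4 (21.7 ± 3.33 to 8.34 ± 1.69 CPM) and Peg13 (9.89 ± 0.891 to 4.37 ± 0.373 CPM). The hypothesis that imprinted genes are lower as a class came from 7 genes already seen to be lower, so it was tested on the other 34 tested genes of a list of 64 imprinted genes written from general knowledge. Of these, 1 was called lower (2.94%, against 4.49% of the genes off the list, Fisher's exact p = 1, two-sided). An odds ratio of up to 3.86 is not excluded. Leaving out genes because they were seen to be lower also lowers the share called among the rest. Over all 41 genes the share was 19.5%, which includes the genes that prompted the hypothesis. Neither share can therefore decide whether imprinted genes are lower as a class.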
